A study of Mus musculus with 8 samples.

How the data were processed

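Messenger RNA from the cerebral cortex of newborn mice of the FVB/N strain was sequenced in 8 libraries, 4 from R342X mutants and 4 from wild-type animals, per the labels. RNA was extracted from frozen tissue with TRIzol and libraries were made with NEBNext dual-index adapters, per the labels' protocols. The labels number the libraries within each genotype and name no animal, litter, sex or batch. Where libraries did not come from separate animals, p-values would measure only the spread between these samples, which may be technical.

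The authors deposited 1 quantification file per library and 1 table of their own comparison. Per the file headers, the deposited library files give, for each transcript, an estimated read count (expected count) that need not be whole and a TPM value, which is scaled by effective transcript length to a fixed sum within each library. Per the submitters' processing notes, Salmon 0.12.0 and DESeq2 were used with the GRCm38 build. Salmon assigns reads to transcripts by a statistical model, so the estimates for transcripts or genes that share sequence depend on one another. The read filters, the bias options and the use of strand are not given in the sources used here. The authors' deposited table gives a mean of normalized counts, read as a signal level, a log2 fold change with its standard error, and a p-value with its adjusted p-value for each gene, per its file header. Its model, its filter and any shrinkage of the folds are not given in the sources used here.

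Transcripts were assigned to genes by the identifiers in the files. Of 136202 transcripts, 134907 (99.0%) matched the GENCODE M21 annotation of GRCm38 in name and version, and the transcripts belonged to 53392 genes, of which 53355 matched. Coordinates, exons, codon positions and gene types come from that annotation. Estimated counts were summed per gene and rounded to whole numbers. Estimated totals ran from 30469745 to 74266937 reads per library, and each wild-type library was deeper than each mutant library, so low-expressed genes were measured with more counts in wild type. Gene levels are given as CPM after TMM scaling. At least 99.9% of each library's counts fell in the 20097 genes that passed edgeR's default filter on low counts.

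Genotypes were compared with edgeR 4.0.16 in R 4.3.3 (TMM scaling, quasi-likelihood F test, genotype as the only term, two-sided), and Benjamini-Hochberg adjusted p-values under 0.05 counted as calls. Standard errors of log2 fold changes were derived from the fold and its F statistic. Phf6, as the gene that carries the mutation, was also tested by exact two-sided permutation of log2 CPM over all 70 assignments of the 8 libraries, and its transcripts by the same test on TPM and on shares of Phf6 TPM. With 4 libraries against 4, the smallest p that this test can give is 0.0286.

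Gene lists (31 lists, 508 entries) of cortical cell types, neighbouring brain regions, blood, meninges, vessels, stress, cell cycle, synapse, axon guidance and PHF6-related functions were fixed before the data were examined, as were the main tests, the rule for named genes and most alternatives. Lists were tested with camera (limma 3.58.1) against all other tested genes, with its preset correlation of 0.01 between members, two-sided, adjusted over the 31 lists, and again with the correlation estimated from the data. The fry test, which sets each list against no change rather than against other genes, was run as an alternative on genotype alone. Counts of called members are given over all genes tested and adjusted over the list alone. Chromosomes were compared by two-sided Fisher's exact tests of called against all tested genes, adjusted over chromosomes, and a window of 10 Mb on each side of Phf6 was tested likewise.

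Named genes followed a fixed rule. Phf6 came first. Then came up to 12 protein-coding genes per direction with the largest fold among calls of average log2 CPM of at least 1 whose mutant and wild-type libraries did not overlap. Predicted genes named Gm or Rik and the Sex-linked list were excluded. Where fewer than 5 genes passed in a direction, the 5 with the smallest p in that direction were named with their values. Of each list, called members (at most 4) or otherwise the member with the smallest p were named. The values of 1 gene so chosen are not reported here, though it remains in the counts and list tests. The rule was applied, after the data were seen, to a second fit, where libraries were required not to overlap within each library set rather than over all 8 libraries.

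That second fit was added because the 8 libraries fell into 2 sets on the first principal component of log2 CPM (prior count of 2). It holds the library set as a term beside genotype. Alternatives covered DESeq2 1.42.0 size factors and Wald test, no filter or a stricter one (5 CPM in at least 4 libraries), limma-voom, offsets for average transcript length, robust dispersion, 1 surrogate variable (sva 3.50.0), X and Y genes left out, each library left out in turn, other thresholds, counts thinned to equal depth (added after the data were seen), and replicate number as a block. Python 3.11.15 with scipy 1.17.1 served for the exact tests.

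The fits were tested on simulated counts for all 20097 genes, drawn from the means and sizes of the real libraries, with 200 genes changed by a known fold. For R342X mutant against wild type, the fit on genotype alone called 39.0% of 100 genes changed by a log2 fold of 0.5 and 63.0% of 100 changed by a log2 fold of 1, with 1 false call. With the library set as a term it called 53.0% and 71.0%, with 14 false calls. The simulated sets were known, whereas the real sets were read from the same values that were tested. False calls that come from choosing the sets are therefore not shown. The list test called the changed list in both fits and none of 20 unchanged lists. Simulated genes were drawn independently of one another, so this does not show how the list test behaves where members are correlated. No pair of libraries in a genotype agreed within sampling noise (chi-square per degree of freedom between 4.33 and 44.9), which does not show whether they came from separate animals. Each library was counted as 1 sample, as the labels number them. Intervals from counting alone were not used, since the files hold no molecular identifiers.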

Results

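Cortical gene expression was compared between newborn mice (postnatal day 0, FVB/N strain) that carry the R342X mutation in Phf6 and wild-type mice, with 4 libraries per genotype. Phf6 is an X-linked gene for a nuclear protein with zinc fingers of the PHD type, and its loss in humans underlies Börjeson-Forssman-Lehmann syndrome, a form of X-linked intellectual disability. The comparison asks which transcripts differ in the cortex of mutants. Mutant replicates 1 to 4 held 39453169, 30469745, 36100264 and 33696020 estimated reads, and wild-type replicates 1 to 4 held 48841467, 62933780, 74266937 and 65416745. Of 53392 genes in the files, 20097 had enough counts to be tested.

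Phf6 itself was lower in every mutant library. Its level was 42.6, 39.3, 43.1 and 43.6 CPM in mutant replicates 1 to 4 and 91.9, 77.8, 74.3 and 72.1 CPM in wild-type replicates 1 to 4. The means were 42.2 ± 1.93 CPM in mutants and 79.0 ± 8.87 CPM in wild type (SD, n = 4 each), so mutants held 53.4% of the wild-type level. The log2 fold change was -0.90 ± 0.08 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00226). An exact two-sided permutation test of log2 CPM gave p = 0.0286, the smallest that 4 against 4 libraries allow. The labels name no sex. In all 8 libraries Xist was at most 0.664 CPM and the Y-linked Ddx3y at least 54.5 CPM, which argues against female RNA. Phf6 (ENSMUSG00000025626) lies on the plus strand of chromosome X from 52912266 to 52956943 in GRCm38. The mutated codon of R342X, CGA in the reference, occupies positions 52953507 to 52953509 in exon 10 of the 11 exons of the main transcript (ENSMUST00000078944.12), which encodes 364 amino acids. It lies 69 bases upstream of the last exon junction.

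The transcripts of Phf6 did not move together. The main transcript, which carried 96.8% ± 0.37 of Phf6 TPM in wild type (SD, n = 4), was at 17.6 ± 0.62 TPM in mutants and 32.7 ± 5.68 TPM in wild type. A shorter transcript (ENSMUST00000101587.9) runs from 52912295 to 52948500, reads on past exon 9 into intron 9, and ends before the mutated codon. Its level was 1.06 ± 0.12 TPM in mutants and 0.43 ± 0.03 TPM in wild type, 2.50-fold higher in mutants, with each mutant library above each wild-type library. Its share of Phf6 TPM was 5.63% ± 0.70 in mutants and 1.29% ± 0.27 in wild type. Another transcript (ENSMUST00000154864.3), which holds the mutated codon, was at 0.10 ± 0.10 TPM in mutants and 0.48 ± 0.14 TPM in wild type (SD, n = 4 each). Exact permutation gave p = 0.0286 for the TPM of each of these 3 transcripts (0.0381 after adjustment over the 4 transcripts with reads), the smallest p possible, and p = 0.0286 for the share of the short transcript (0.0571 after adjustment). These values rest on few reads for the short transcript, between 35.1 and 79.0 estimated reads per library, and the error of their assignment to transcripts is unknown.

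**Figure D1:**
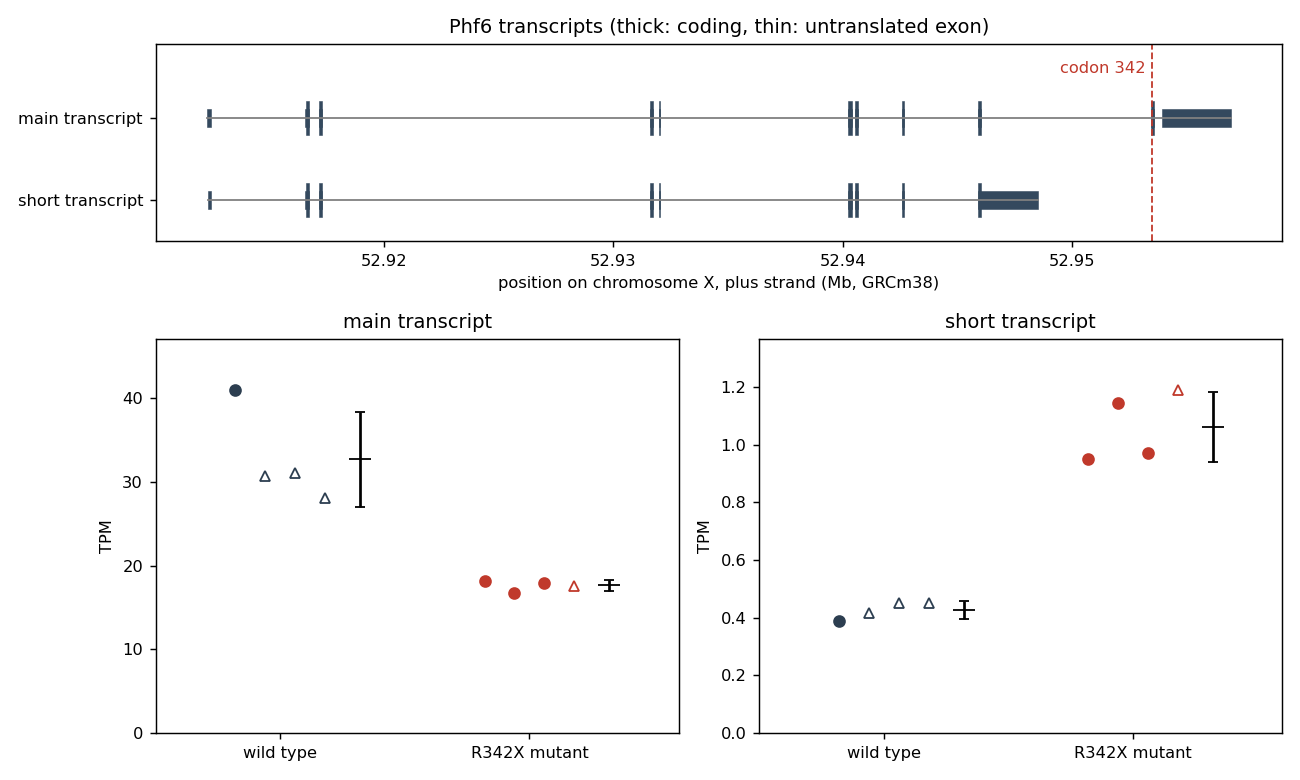
The main and the short Phf6 transcript drawn to scale on chromosome X (GRCm38, position in Mb), with the mutated codon as a dashed line, above the TPM of each transcript in each library. Filled circles are libraries of set 1, open triangles libraries of set 2, and bars show the mean and SD of 4 libraries per genotype. The main transcript was lower and the short one higher in each mutant library than in each wild-type library.

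The 8 libraries fell into 2 sets that followed genotype only in part. The first principal component carried 35.3% of the variance and placed mutant replicates 1 to 3 with wild-type replicate 1 (set 1) and mutant replicate 4 with wild-type replicates 2 to 4 (set 2). With genotype held in the model, 6295 genes differed between the sets (edgeR, adjusted p under the 0.05 threshold). The sets were drawn from these same values, so a large count follows from their definition. The p-values therefore do not test whether the sets exist. Retained-intron transcripts took between 3.67% and 3.87% of reads in set 1 and between 4.05% and 4.22% in set 2. The labels name no batch, so the sets are described here from the data alone, and for some genes the difference within each set is given as well. Each set holds 1 library of a genotype and 3 of the other, so a difference within a set has no replicate on that side. Genotype and set are therefore partly mixed, and differences on genotype alone carry part of the difference between the sets.

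**Figure D2:**
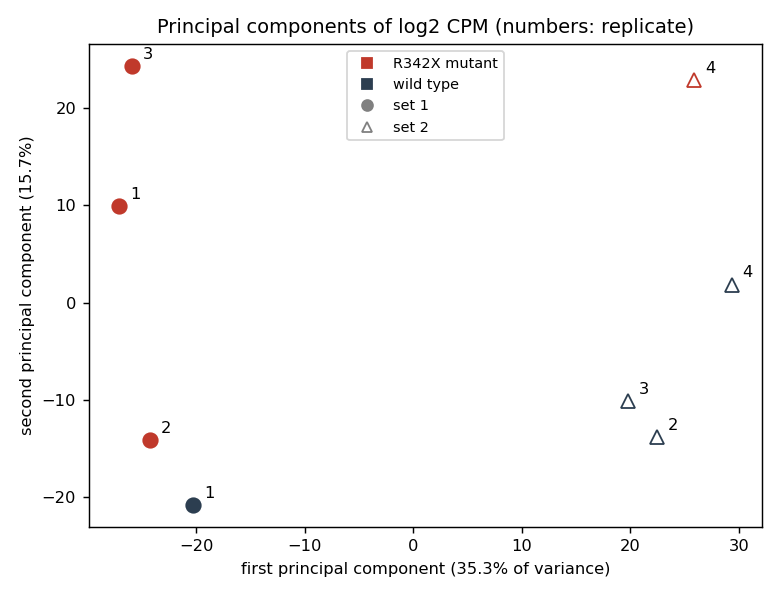
First and second principal components of log2 CPM over the tested genes, 1 point per library with its replicate number. Colour gives the genotype, and filled circles and open triangles mark set 1 and set 2. The first component (35.3% of variance) separates the sets, each of which holds both genotypes.

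Between genotypes, 4 genes changed, all 4 were lower in mutants, and all 4 lie on chromosome X. Cldn34c1, a gene of the claudin family of tight-junction proteins (ENSMUSG00000079450, X, 123103495 to 123188795), fell from 20.4 ± 0.98 to 0.92 ± 0.13 CPM (SD, n = 4 each), 4.52% of the wild-type level, with a log2 fold change of -4.46 ± 0.11 (SE; edgeR adjusted p = 1.57e-08). Within the sets its log2 difference was -4.41 in set 1 and -4.30 in set 2. Arhgap4, which encodes a GTPase-activating protein (ENSMUSG00000031389, X, 73891442 to 73921870), fell from 7.04 ± 0.68 to 3.36 ± 0.22 CPM, with a log2 fold change of -1.07 ± 0.11 (adjusted p = 0.00566) and log2 differences of -1.23 and -0.95 in set 1 and set 2. Haus7, a subunit of the augmin complex of the mitotic spindle (ENSMUSG00000031371, X, 73437315 to 73459044), fell from 26.9 ± 1.35 to 17.0 ± 0.36 CPM, with a log2 fold change of -0.66 ± 0.06 (adjusted p = 0.00226) and log2 differences of -0.56 and -0.71. Phf6 was the remaining gene, with log2 differences of -1.14 in set 1 and -0.78 in set 2. Arhgap4 overlaps Naa10, Avpr2 and L1cam in the annotation, so its counts are less certain.

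**Figure D3:**
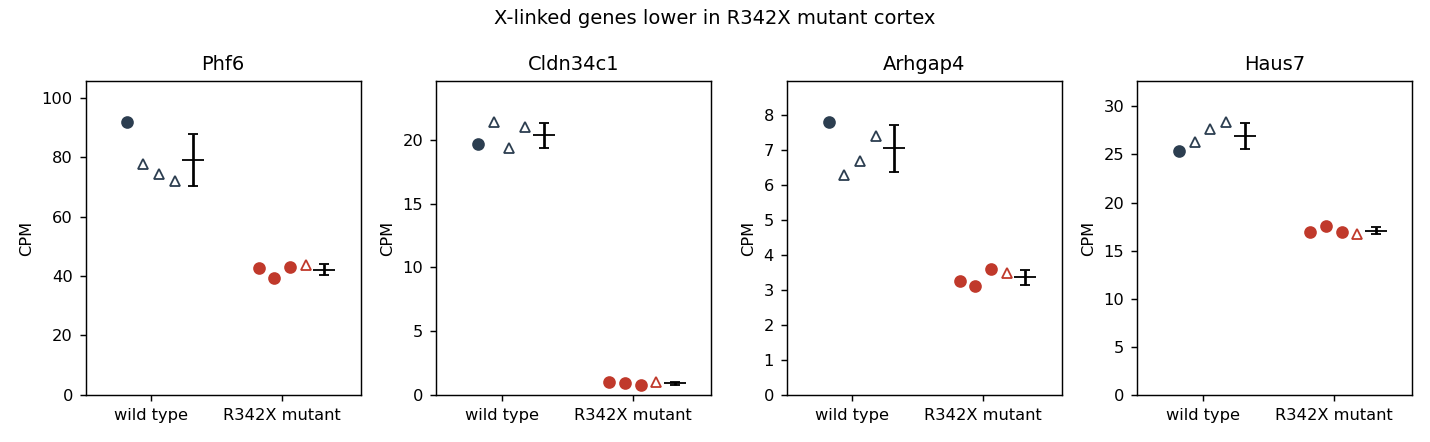
Level in CPM of Phf6, Cldn34c1, Arhgap4 and Haus7 in each library, with wild type on the left and R342X mutant on the right of each panel. Filled circles are set 1, open triangles set 2, and bars show mean and SD of 4 libraries. Mutant and wild-type libraries do not overlap for any of the 4 genes, and Cldn34c1 was at most 1.03 CPM in the mutants.

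Chromosome X held 637 (3.17%) of the tested genes and 4 of 4 calls (Fisher's exact test, two-sided, adjusted p = 2.21e-05 over chromosomes). Phf6 is X-linked by design. With it left out of the calls and the tested genes, a test chosen after seeing the data, X held 3 of 3 calls (unadjusted p = 3.16e-05). Apart from Phf6, none of the 70 tested genes within 10 Mb of Phf6 was called.

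No gene rose past the threshold. In the edgeR fit on genotype alone 2758 genes had an unadjusted p under 0.05, and DESeq2's Wald test on the same counts called 228 genes as higher and 173 as lower. The genes closest to the threshold on the higher side were Cdkn1a, the p21 inhibitor of the cell cycle (log2 fold change 0.49 ± 0.06, adjusted p = 0.0529), Sncb, the gene for beta-synuclein (0.36 ± 0.05, adjusted p = 0.0846), and Itgb3, Eng and Vsnl1, for integrin beta 3, the endothelial receptor endoglin and the neuronal calcium sensor visinin-like 1 (0.84 ± 0.13, 0.38 ± 0.06 and 0.50 ± 0.08, adjusted p = 0.133 each). The log2 difference of Sncb was 0.48 in set 1 and 0.22 in set 2, and that of Vsnl1 0.50 and 0.25. On the lower side Gipr, a receptor for an incretin hormone, stood at -0.55 ± 0.08 (adjusted p = 0.0846). The count of calls changed with single libraries: it was 720 without mutant replicate 4 and 13 without wild-type replicate 1. Each of these libraries is the lone library of its genotype in its set. Without it the genotypes lie closer to the library sets, so more of the set difference can enter the count. Of the 720 calls, 61 were among the 121 of the fit with the library set as a term, described below. Without mutant replicate 2 Arhgap4 missed the threshold (adjusted p = 0.0536).

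The synaptic, immediate early, astrocyte and oligodendrocyte lists were shifted upward in mutants by camera with its preset correlation, and none of these calls held with an estimated one (adjusted p = 0.443, 0.345, 0.345 and 0.443 in that order). In each of the 4 lists mutant replicate 4 stood below wild-type replicate 1, with mean log2 levels of -0.047, -0.017, -0.004 and -0.056 against 0.029, 0.082, 0.009 and 0.093. Of 32 synaptic genes, 28 had a log2 fold change above 0 (median 0.11, camera adjusted p = 2.30e-06), 10 were higher and 1 was lower when adjusted over the list alone, and none passed over all genes. Camk2a, a kinase of the postsynaptic density, had the smallest p of the list (log2 fold change 0.25 ± 0.05, adjusted p = 0.159 over all genes). Immediate early genes, which neurons switch on with activity, had a median of 0.30 with 17 of 18 members above 0 (adjusted p = 3.87e-05). Fos stood at 0.49 ± 0.13 (adjusted p = 0.232), and no member passed, over all genes or adjusted over the list alone. Astrocyte genes had a median of 0.22 (9 of 12 above 0, adjusted p = 0.000119), with 6 members higher when adjusted over the list alone, led by the lipid carrier Apoe (0.30 ± 0.07). Oligodendrocyte lineage genes had a median of 0.21 (11 of 13 above 0, adjusted p = 0.00111), with 3 members higher when adjusted over the list alone, among them the precursor receptor Pdgfra (0.17 ± 0.05). Choroid plexus and ependyma genes (median 0.14, adjusted p = 0.0345) and hippocampal genes (median 0.08, adjusted p = 0.0433) were also called, with 0 members of the first and 1 of the second (Etv1, 0.27 ± 0.07) higher over the list alone. Prlr stood at 0.50 ± 0.17 in the choroid plexus list. With an estimated correlation the adjusted p was 0.443 for the hippocampal list and 0.483 for choroid plexus. With the library set as a term, a fit added after the data were seen and described below, the oligodendrocyte (median 0.09, adjusted p = 0.0647) and hippocampal (median 0.16, adjusted p = 0.0899) calls were lost, and the median of the immediate early list fell to 0.14 (adjusted p = 0.000565).

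Lists of dividing progenitors were shifted downward by camera with its preset correlation. With an estimated correlation no call of this paragraph held: the adjusted p was 0.111 for intermediate progenitors and 0.443 for the other 5 lists. Intermediate progenitors, the basal dividing cells that give rise to cortical neurons, had 9 of 11 genes below 0 (median -0.19, camera adjusted p = 0.000107), and 3 were lower when adjusted over the list alone, of which Sstr2, a somatostatin receptor, stood at -0.38 ± 0.06 (adjusted p = 0.138 over all genes). Cell cycle genes had 27 of 30 members below 0 (median -0.17, adjusted p = 0.000107), with 0 passing over the list alone. In this list mutant replicate 4 stood apart, with a mean log2 level of 0.170 against -0.255 to -0.126 in the other mutants and 0.022 to 0.194 in wild type. Mcm7, part of the replicative helicase, stood at -0.30 ± 0.08. Radial glia genes had a median of -0.12 (13 of 16 below 0, adjusted p = 0.00754), with only Nes, the gene for nestin, lower over the list alone (-0.24 ± 0.05). The 13 mitochondrially encoded genes had a median of -0.19 (12 below 0, adjusted p = 0.000151, 0 over the list alone), with mt-Cytb at -0.22 ± 0.09. The list of PHF6 family and X-linked intellectual disability genes, to which Phf6 itself belongs, had a median of -0.05 (12 of 20 below 0, adjusted p = 0.00265), with 4 members lower over the list alone and Phf6 lower over all genes. The list was not tested without Phf6 in either fit, so its call does not show a shift of the other members. The 5 sex-linked genes tested had a median of -0.43 (adjusted p = 0.00164), 1 of them, Ddx3y, lower over the list alone (-0.60 ± 0.13). Wild-type replicate 1 stood apart in this list, with a mean log2 level of 0.73 against -0.14 to 0.13 in the other wild-type libraries. With the library set as a term the radial glia (median -0.04, adjusted p = 0.0552) and mitochondrial (median -0.08, adjusted p = 0.144) calls were lost, and the cell cycle median shrank to -0.07 (adjusted p = 0.0426). Retained-intron share and depth differed between libraries as given above. Without mutant replicate 4 the hippocampus (adjusted p = 0.221), choroid plexus (0.431) and PHF6 family (0.073) lists were not called. The last of these was also lost without wild-type replicate 1 (0.129), choroid plexus without wild-type replicates 2 (0.112) or 4 (0.0769), and hippocampus without wild-type replicate 4 (0.256).

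The other 19 lists were not called. Ribosome biogenesis genes had a median of -0.04 (adjusted p = 0.0618; Ubtf -0.14 ± 0.04), interferon response genes 0.14 (0.0764; Ifit3 0.74 ± 0.21), meningeal fibroblast genes 0.14 (0.0794), and microglial genes 0.13 (0.0905; C1qc 0.24 ± 0.11). The adjusted p was 0.160 for the NuRD and PAF1 complexes that bind PHF6 (median -0.03; Chd4 -0.16 ± 0.06) and for heat shock genes (median 0.19; Ddit4 -0.20 ± 0.05). The fry test, which sets a list against no change rather than against other genes, gave the NuRD and PAF1 list an adjusted p of 0.0469. The camera adjusted p was 0.302 for endothelial cells and pericytes (median 0.08; Cspg4 0.25 ± 0.08) and 0.306 for neuropeptides (median 0.09; Crh 1.29 ± 0.30). It was 0.318 for Cajal-Retzius cells (median -0.05; Nhlh2 -0.36 ± 0.10) and for hypoxia genes (median 0.02; Slc2a1 0.19 ± 0.05), and 0.361 for red blood cells (median 0.03). Interneurons (median -0.04; Gad2 -0.38 ± 0.09), striatum (median 0.11; Ppp1r1b -0.12 ± 0.07), upper layer neurons (median -0.01; Pou3f3 -0.29 ± 0.06) and deep layer neurons (Nr4a2 0.26 ± 0.08) each had an adjusted p of 0.391. Eph receptors and ephrins (median 0.04, Epha3 -0.29 ± 0.05) had an adjusted p of 0.710, semaphorins, plexins and other axon guidance genes (median 0.02) 0.805, and p53 targets (median -0.04) and thalamus and hypothalamus genes (median 0.03; Rgs16 -0.34 ± 0.08) 0.978 each. The camera direction was opposite in sign to the median for the Eph, semaphorin, deep layer and thalamus lists. Some of these lists were called when 1 library was left out. Meningeal genes were higher without mutant replicates 1 (0.0187), 2 (0.0301) or 3 (0.00324) or wild-type replicates 3 (0.0158) or 4 (0.00239), microglial genes without mutant replicates 1 (0.0151) or 2 (0.0348) or wild-type replicate 3 (0.0239), and interferon genes without mutant replicates 1 (0.0343) or 2 (0.0301). Ribosome biogenesis genes were lower without mutant replicate 1 (0.0343) or wild-type replicate 1 (0.0302), and striatal genes were higher without wild-type replicate 1 (0.0382) and red blood cell genes without wild-type replicate 2 (0.00346).

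**Figure D4:**
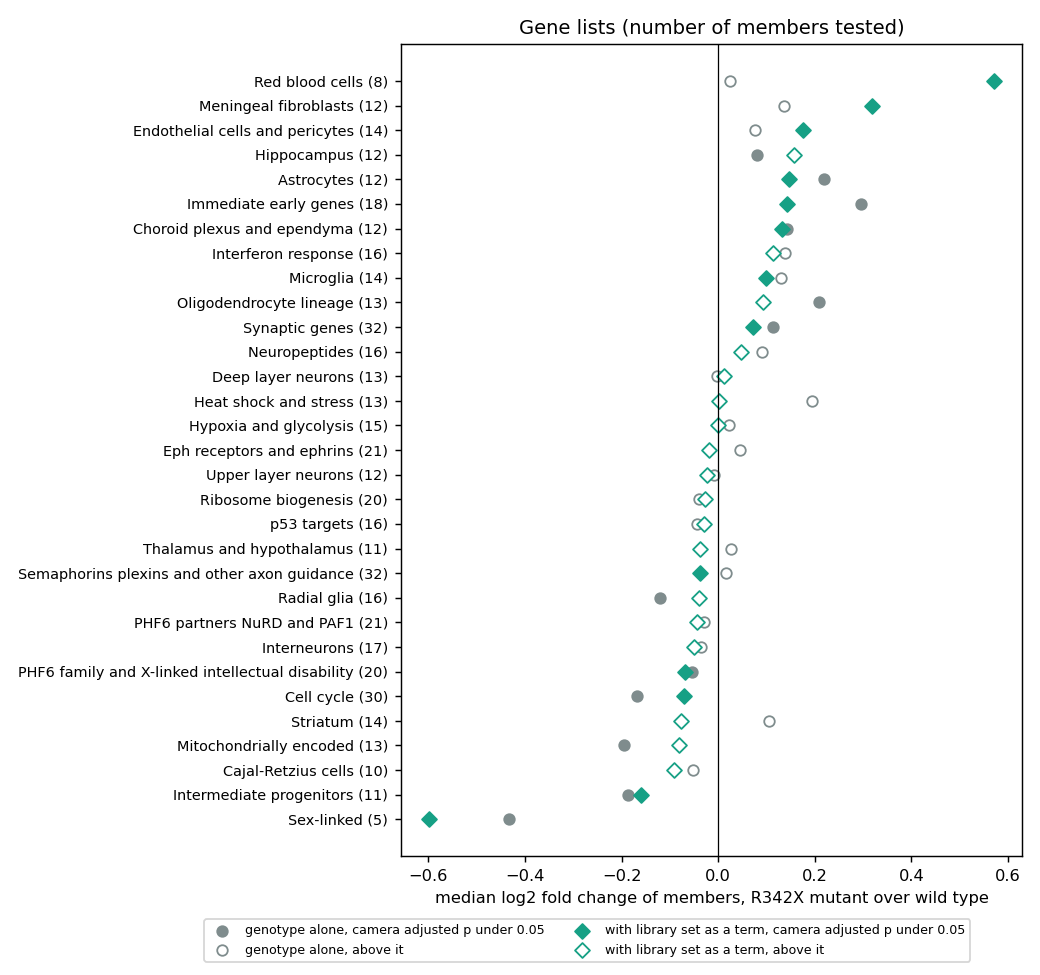
Median log2 fold change (R342X mutant over wild type) of the members of each gene list, with the number of members tested. Grey circles come from the fit on genotype alone and green diamonds from the fit with the library set as a term, filled where camera's adjusted p is under 0.05 with its preset correlation. Red blood cell, meningeal and endothelial lists had their medians at 0.57, 0.32 and 0.17 with the set as a term, against 0.03, 0.14 and 0.08 without it.

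With the library set held as a term, an analysis chosen after seeing the data, 121 genes changed between genotypes, 48 higher and 73 lower, and these included the 4 X-linked genes. The genes that rose included 2 of the meningeal fibroblast list, Aldh1a2 and Igf2, and 0 of the endothelial and pericyte list. Acta2, the smooth muscle actin of mural cells, had a log2 fold change of 0.89 ± 0.17 (edgeR adjusted p = 0.0422). F13a1, a coagulation factor subunit made by border macrophages, rose by 0.69 ± 0.08 (adjusted p = 0.00689), with log2 differences of 0.73 in set 1 and 0.65 in set 2. The growth factors Igf1 (0.59 ± 0.10; 0.36 in set 1 and 0.80 in set 2) and Igf2 (0.57 ± 0.09; 0.37 and 0.76) rose, and both lost their call without mutant replicate 4 (adjusted p = 0.282 and 0.234) and without some of the other libraries. Also higher was Aldh1a2, the retinoic acid synthesis enzyme of the meninges (0.48 ± 0.06, adjusted p = 0.011). Among the 12 genes named in this direction were also Itgb3 (0.75 ± 0.13), the phospholipase gene Pla2g3 (0.84 ± 0.14), the flow-responsive endothelial factor Klf2 (0.57 ± 0.11), Mrgprf (0.54 ± 0.11), the Notch target Heyl (0.51 ± 0.09), Hif3a (0.49 ± 0.09) and Cdkn1a (0.48 ± 0.06). Within the sets Cdkn1a differed by 0.49 and 0.46 and Aldh1a2 by 0.46 and 0.50, whereas Acta2 differed by 0.40 in set 1 and 1.29 in set 2. Pooled over the sets, mutant and wild-type libraries overlapped for F13a1, Klf2, Igf2, Mrgprf, Heyl, Hif3a and Aldh1a2, and on genotype alone the log2 fold change was 0.24 for F13a1 (adjusted p = 0.657), 0.22 for Mrgprf (0.613), 0.27 for Klf2 (0.512), 0.36 for Igf2 (0.362), 0.33 for Heyl (0.330), 0.34 for Hif3a (0.283) and 0.29 for Aldh1a2 (0.344). Of the 30 genes named from this fit, Phf6, Cldn34c1 and Haus7 alone kept their call without each library in turn.

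Genes of neuronal progenitors and axon guidance were among those that fell with the set as a term. Neurog2, a proneural transcription factor, fell by 0.54 on the log2 scale (SE 0.10, adjusted p = 0.0363), Sstr2 by 0.44 (SE 0.05, adjusted p = 0.00689) and Insm1, a zinc finger factor of basal progenitors, by 0.32 (SE 0.05, adjusted p = 0.0208). Sstr2 differed by -0.44 in both sets, and Insm1 by -0.43 in set 1 and -0.22 in set 2. The secreted guidance factor Sema3c (-0.38 ± 0.07), the axonal adhesion molecule Cntn2 (-0.29 ± 0.05; -0.41 in set 1 and -0.18 in set 2, and not called without some libraries, with an adjusted p of up to 0.380 without wild-type replicate 1), the ephrin receptor Epha3 (-0.29 ± 0.05) and Pou3f3, a factor of upper layer neurons (-0.21 ± 0.04; -0.28 and -0.15 in the sets, and -0.14 with an adjusted p of 0.389 without wild-type replicate 1), were lower too. The 12 genes named in this direction were Cldn34c1, Arhgap4, Phf6, Haus7, Neurog2, Sstr2, Gipr (-0.47 ± 0.06), Ackr3, a scavenger receptor for a chemokine of migrating neurons (-0.42 ± 0.07), the X-linked Armcx1 (-0.44 ± 0.07), the calcium release channel gene Ryr1 (-0.52 ± 0.08), the muscle filament gene Neb (-0.53 ± 0.10) and Rpl34 (-1.31 ± 0.25). Rpl34 encodes a ribosomal protein with many near-identical copies in the genome, so its reads are uncertain. Its level was 93.8, 108.8, 109.3 and 42.9 CPM in wild-type replicates 1 to 4 and between 32.3 and 39.8 CPM in mutants. Wild-type replicate 4 thus lay near the mutants. The log2 differences in set 1 and set 2 were -0.71 and -0.32 for Ryr1, -0.30 and -0.60 for Armcx1 and -0.66 and -0.36 for Neb, whose libraries overlapped between genotypes when pooled. Offsets for average transcript length left 14 calls, 13 of them among the 121 and 8 of them among the 30 genes named from this fit (Phf6, Cldn34c1, Arhgap4, Haus7, F13a1, Cdkn1a, Aldh1a2 and Sstr2). Without wild-type replicate 1 there were 20 calls, 7 of them among the 121, and without mutant replicate 4 there were 54, 29 of them among the 121. Each of these leaves a set with a single genotype, so the effect then rests on the other set. Without each of the other libraries the count was 40, 21 and 46 (mutant replicates 1 to 3) and 59, 68 and 130 (wild-type replicates 2 to 4).

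Among the lists in this fit, those of meninges and vessels lay higher and those of intermediate progenitors and axon guidance lower, though no call held with an estimated correlation, as given below. Meningeal fibroblast genes had 11 of 12 members above 0 (median 0.32, camera adjusted p = 2.91e-12), with 2 higher over all genes (Aldh1a2 and Igf2) and 8 adjusted over the list alone. Endothelial and pericyte genes had 12 of 14 above 0 (median 0.17, adjusted p = 4.94e-08), 9 of them higher adjusted over the list alone. The mean log2 level of the meningeal list was 0.391 in mutant replicate 4, -0.103 to -0.004 in the other mutants and -0.234 in wild-type replicate 1, and that of the endothelial list was 0.203, -0.080 to 0.015 and -0.148. In wild-type replicates 2 to 4 the level was -0.203, 0.056 and 0.137 for the meningeal list and -0.072, 0.080 and 0.043 for the endothelial list. All 8 red blood cell genes were above 0 (median 0.57, adjusted p = 0.000396), with 0 passing over the list alone. The mean log2 level of this list was 0.197, -0.156, -0.194 and 0.448 in mutant replicates 1 to 4. In wild-type replicates 1 to 4 it was -0.912, 0.742, -0.450 and 0.325. Microglial genes had a median of 0.10 (adjusted p = 0.0323). Intermediate progenitor genes had 9 of 11 below 0 (median -0.16, adjusted p = 4.17e-07), 3 lower over all genes and 6 over the list alone, and the semaphorin, plexin and axon guidance list had 20 of 32 below 0 (median -0.04, adjusted p = 0.0147), with 6 lower and 1 higher over the list alone. With an estimated correlation the adjusted p was 0.262 for meningeal, 0.265 for endothelial, 0.498 for red blood cell, 0.550 for microglial, 0.177 for intermediate progenitor and 0.550 for axon guidance genes. The synaptic (median 0.07), astrocyte (0.15), immediate early (0.14), choroid plexus (0.13), cell cycle (-0.07), sex-linked (-0.60) and PHF6 family (-0.07) lists were called in the same direction as without the term, with adjusted p of 0.55, 0.265, 0.262, 0.55, 0.64, 0.262 and 0.262 in that order with an estimated correlation. Without wild-type replicate 1 the red blood cell call was lost (adjusted p = 0.344) and the direction of the axon guidance list turned (0.948); the axon guidance call was lost without mutant replicates 1 (0.0593) or 3 (0.0511). The microglial call was lost without mutant replicates 3 (0.0995) or 4 (0.3002) or wild-type replicate 4 (0.0739), the cell cycle call without mutant replicates 1 (0.0707), 2 (0.168) or 3 (0.0508) or wild-type replicate 4 (0.129), and the choroid plexus call without wild-type replicates 2 (0.0624) or 4 (0.0572), while the cell cycle list turned without wild-type replicate 1 (0.0767) and choroid plexus without mutant replicate 4 (0.335). Lists not called in this fit were called without mutant replicate 3 (interneurons 0.0182, mitochondrial 0.0373, oligodendrocyte 0.0415, radial glia 0.0130), mutant replicate 4 (radial glia 0.00871, striatum 0.0375), wild-type replicate 1 (hippocampus 0.00359, mitochondrial 0.00333), wild-type replicate 3 (hippocampus 0.0422, mitochondrial 0.0183, oligodendrocyte 0.0301, striatum 0.0159) or wild-type replicate 4 (radial glia 0.0224).

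Of the 121 genes, 14 lie on chromosome X, where 3.17% of tested genes lie (odds ratio 4.06, 95% interval 2.14 to 7.17, adjusted p = 0.000661 over chromosomes, Fisher's exact test). The 10 X-linked genes beyond the 4 called on genotype alone were Agtr2, Mid2, Col4a5 and Kcne1l, which were higher, and Gpc4, Nsdhl, Drp2, Armcx1, Gucy2f and Lrch2, which were lower; they are listed because of where they lie, after their values were seen. Chromosome Y held 2 of the 121 genes, Ddx3y (-0.64 ± 0.13; -1.07 in set 1 and -0.18 in set 2, and -0.17 with an adjusted p of 0.406 without wild-type replicate 1) and the predicted gene Gm29650 (-0.73 ± 0.15), against 15 of all tested genes (adjusted p = 0.0395, Fisher's exact test). Gpc4, from 52053021 to 52165252, was the only one of these 10 within 10 Mb of Phf6 (Fisher's exact test for that window, odds ratio 2.42, p = 0.343).

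The authors' deposited table lists 24494 genes, of which 417 had an adjusted p under 0.05, 219 higher and 198 lower. In the authors' deposited table Phf6 has a log2 fold change of -0.93, Cldn34c1 -3.96, Arhgap4 -1.31 and Haus7 -0.58, and all 4 genes called here on genotype alone are among its calls in the same direction. Its folds may be shrunk, since Rpl34 stands there at -0.022 ± 0.055 (SE) with an adjusted p of 0.0224. They therefore need not match the edgeR folds in size. Of the 121 genes called with the library set as a term, 107 are among the calls of the authors' deposited table, each in the same direction. Across 20093 genes, which are not independent replicates, the Spearman correlation of signed log10 p with the authors' deposited table was 0.62 on genotype alone and 0.90 with the set as a term. The Spearman correlation of log2 fold changes, the measure planned, was 0.48 and 0.74 in that order.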

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

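The tests on a possible batch term in the authors' model, which is not given, and on the Y-linked genes were chosen only after the result was seen. Among 192 groups of 4 libraries, 24 held a library whose gap to the nearest of the other 3 took a larger share of the group's range than Dixon's 95% critical value, which chance gives in about 1 group in 20. The groups share libraries, and many of the genes were chosen from these same values. The 24 therefore cannot be weighed against that rate. Of the 24, 15 were in mutant replicate 4 and 6 in wild-type replicate 1, each the lone library of its genotype in its library set.

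In mutant replicate 4, the level in CPM (with the median of the other 3 mutant libraries) was 6.31 (3.65) for Acta2, 25.3 (14.1) for F13a1, 5.28 (3.45) for Mrgprf, 32.5 (24.4) for Aldh1a2, 29.9 (21.3) for Ryr1, 25.5 (32.9) for Armcx1, 422 (360) for Chd4 and 128 (111) for Nes. In the same library it was 72.2 (55.8) for Ddx3y, 160.4 (174) for Camk2a, 405 (348) for Pou3f3 and 63.3 (45.8) for Insm1. Its mean log2 level was 0.154 (0.0347) for the hippocampus list and -0.0561 (0.160) for the oligodendrocyte list. In wild-type replicate 1 the level was 63.9 (59.2) for Vsnl1, 2.31 (3.58) for Mrgprf, 13.8 (12.2) for Ackr3, 117 (82.9) for Ddx3y, 62.8 (73.3) for Insm1 and 33.8 (12.7) for Uty. Gipr stood at 73.0 (62.7) CPM in wild-type replicate 4. The mean log2 level was -0.0837 (0.00923) for the p53 list in mutant replicate 2 and -0.156 (-0.0397) for the interferon list in wild-type replicate 3.

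The 2 library sets stayed apart after every library was thinned to equal depth, with a gap of 0.728 of the range of the first component, which argues against depth as their cause. Across genes, the difference between the sets had a Spearman rho of -0.175 with transcript length and 0.0473 with GC content, too large to exclude a bias, so a length bias cannot be told apart from other causes. A DESeq2 fit with length offsets and the sets as a term ranked genes as the authors' deposited table does (rho of 1.00 for signed log10 p, against 0.683 without the term). A batch that the authors' model held as a term is therefore a candidate explanation. No biological explanation was tested, since the labels give no group that follows the sets.

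Y-linked transcripts were high in wild-type replicate 1: its level over the median of the other 7 libraries was 1.88 for Kdm5d, 2.49 for Uty, 1.63 for Ddx3y, 1.92 for Eif2s3y and 1.19 for Uba1y. Mutant replicates 1 to 3, of the same set, had a median ratio of 0.878 to set 2 over these 5 genes, which argues against the sets as the cause. Xist was at most 0.664 CPM in the 8 libraries, which argues against female RNA in the others, and this library ranked 5 of 8 in depth, which argues against depth. What remains open is a difference of the animal itself, which was not tested.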

How the results depend on the processing

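The library set as a term, thinning to equal depth and all alternatives of the set-term fit were chosen only after the result was seen. Phf6 kept its call and direction under every alternative that tested it (leaving out X and Y genes leaves it out), with a log2 fold change between -0.95 and -0.82 without the set term and between -1.14 and -0.77 with it. The 4 calls on genotype alone also came as 4 with limma-voom, robust dispersion, thinning and a threshold of 0.01. The other counts of genes changed (higher, lower) were 5 (1, 4) with DESeq2 size factors, with the stricter filter and with length offsets, 13 (5, 8) without a filter, 401 (228, 173) with DESeq2's Wald test, 302 (147, 155) with 1 surrogate variable, 7 (2, 5) at a threshold of 0.10 and 121 (48, 73) with the library set as a term. With X and Y genes left out edgeR called 0 (0, 0), with 2657 genes at an unadjusted p under 0.05. With each library left out the count ran from 3 to 720, from 0 to 362 higher and from 3 to 358 lower. The cause was not tested, except that the X and Y setting leaves out the 4 called genes by its construction. The 720 calls came without mutant replicate 4, where the genotypes lie closer to the library sets.

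With the library set as a term, the count was 739 (384, 355) without a filter, 497 (273, 224) with DESeq2's Wald test, 14 (6, 8) with length offsets, 244 (115, 129) with robust dispersion, 6 (1, 5) at a threshold of 0.01 and 378 (184, 194) at 0.10. It was 40 (15, 25), 21 (7, 14), 46 (19, 27) and 54 (18, 36) without mutant replicates 1 to 4 and 20 (13, 7), 59 (27, 32), 68 (21, 47) and 130 (53, 77) without wild-type replicates 1 to 4. Of the 30 genes named from this fit, 29 kept their call with DESeq2, 24 with limma-voom, 26 with robust dispersion, 27 after thinning, 8 with length offsets and 6 with replicate number as a block. Over all these genes and left-out libraries, 121 calls were kept and 119 lost. With length offsets the 22 genes that lost their call had an adjusted p between 0.0565 and 0.368.

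Taking replicate number as a block gave 20 (8, 12) on genotype alone and 11 (1, 10) with the set term. The share of X among calls was then 20% (adjusted p = 0.0712). The labels do not say whether libraries of the same number pair. Their correlations across genes were 0.244, -0.0269, -0.0845 and 0.318, against -0.451 to 0.203 for libraries of different number. The positive values come from pairs within 1 library set, so these correlations do not decide whether numbers pair. The difference in share of the short Phf6 transcript was 3.72 points from read numbers and between 4.12 and 4.56 points with each library left out, with an exact p of 0.0571 each, the smallest that 3 against 4 libraries allow.

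Of the list calls on genotype alone, 0 held with an estimated correlation, and with the set term 0 held likewise. On genotype alone fry called intermediate progenitors (adjusted p = 0.0204) and the list of PHF6 partners (0.0469). Fry tests a list against no change, so its calls do not show a difference from other genes. With each library left out 9 to 16 lists were called on genotype alone and 11 to 17 with the set term. Some lists turned direction, all with the adjusted p given. With 1 surrogate variable these were striatum (0.544), thalamus (0.916) and p53 targets (0.9899), and with the library set as a term striatum (0.144), thalamus (0.923) and p53 targets (0.911). On genotype alone they were thalamus without mutant replicate 1 (0.483) and wild-type replicates 3 (0.843) and 4 (0.537), p53 without mutant replicate 2 (0.813) and wild-type replicates 3 (0.913) and 4 (0.912), and axon guidance without mutant replicate 3 (0.967) and wild-type replicate 1 (0.287). Endothelial genes turned without mutant replicate 4 (0.897), Eph genes (0.897) and red blood cells (0.813) without wild-type replicate 1, and striatum without wild-type replicate 3 (0.741). With the set term p53 turned without mutant replicate 1 (0.935) and wild-type replicate 1 (0.888), thalamus without mutant replicates 3 (0.791) and 4 (0.909) and wild-type replicate 2 (0.415), and choroid plexus (0.335), hippocampus (0.947) and mitochondrial genes (0.776) without mutant replicate 4. Cell cycle (0.0767), Eph (0.948), heat shock (0.754), neuropeptides (0.516) and axon guidance (0.948) turned without wild-type replicate 1, and deep layer genes (0.994) without wild-type replicate 4. F13a1 on genotype alone had a log2 fold change of -0.0187 without mutant replicate 4 and up to 0.349 without another library. With each library left out on genotype alone, the adjusted p ran from 0.0544 to 0.897 for endothelial genes, 0.366 to 0.967 for Eph genes, 0.00346 to 0.813 for red blood cells, 0.0724 to 0.979 for axon guidance, 0.0382 to 0.787 for striatum, 0.288 to 0.927 for thalamus and 0.806 to 0.967 for p53 targets. The cause was not tested.

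Calls shared with the authors' deposited table numbered 180 with DESeq2, 210 with DESeq2 and length offsets, 107 with the set term, 318 with the set term in DESeq2, 410 with the set term in DESeq2 and length offsets, and 213 with the replicate block in DESeq2 and length offsets. Depth limits genes of low count most in the mutants, which had fewer reads.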

Other observations

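The tests on the Cldn34 family, on strain variants and on the short Phf6 transcript, and the fit with the library set as a term and its splits, were chosen only after the result was seen.

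Some lists held members that passed in both directions when adjusted over the list alone, in the fit on genotype alone and with no call over all genes. Among upper layer genes, Rasgrf2 (0.43) and Rorb (0.28) had log2 fold changes above 0, and the transcription factors Pou3f2 (-0.30) and Pou3f3 (-0.29) and the netrin receptor gene Unc5d (-0.19) lay below 0. Among heat shock and stress genes, the inducible chaperones Hspa1a (0.76) and Hspa1b (0.60) lay above 0 and Ddit4 (-0.20) below. In the thalamus list, Ntng1 stood at 0.37 and Rgs16 at -0.34. In the PHF6 family list the members that passed over the list alone were all lower: Phf14 (-0.16), Atrx (-0.17) and Kdm6a (-0.21) beside Phf6, which was also called over all genes.

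The 4 genes called on genotype alone lie on chromosome X. All 4 were called after thinning to equal depth, which argues against depth as their cause. The whole Cldn34 family was 21.4 times as high in wild type as in mutants. Its members other than Cldn34c1 held between 0 and 4 counts per library, so reads were not moved to those members. Copies not counted in the family, and reads that matched no transcript, were not examined. Among the other 117 genes called with the set as a term, chromosome X was over-represented (odds ratio 2.88, 95% interval 1.34 to 5.55). Variants on the X chromosome that carries the allele could give this, and so could an effect of PHF6 loss on X-linked genes. Within 20 Mb of Phf6, 1 of 131 tested genes was called with the set term (Fisher's exact test, odds ratio 1.28, p = 0.545). Nsdhl, Haus7 and Arhgap4, called in the same fit, lie close together from 72918557 to 73921870, just beyond that window. The result of the window test therefore depends on where the window ends, and it does not show whether calls crowd near Phf6. The over-representation thus does not tell these explanations apart. Both stay open, since the design does not part the allele from its chromosome.

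The short Phf6 transcript, which lacks the mutated codon, was 2.50 times as high in mutants in TPM, with each mutant library above each wild-type library. Loss of the transcripts that hold the stop codon, with the short one left as it was, would give a ratio near 1, so that explanation is argued against as the whole cause. A higher output of the short transcript, or reads assigned to it by the model, may be involved, and neither was tested.

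Regrouping the 8 libraries shows how far chance can be excluded. On genotype alone, 3 of the 35 splits called at least the 4 genes of the real split, so chance is not excluded for that count. The highest other split called 7096 genes and is the split into the library sets. Those sets were drawn from the same values, so this count adds no separate evidence for them. For the lists, 6 of the 35 splits called at least the 12 of the real one, the highest other 15, so chance is not excluded. With the set as a term, groups of the real make-up can be formed within the sets in 16 ways, too few for a share under 0.05; the real split called 121 genes and the highest other called 1. In simulated data with known sets, the same fit made 14 false calls beside 53 and 71 true ones, a larger share than its threshold allows.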
